A study of Drosophila melanogaster with 4 samples.

How the data were processed

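The data were 4 single-colour Affymetrix expression arrays of fat bodies dissected from Drosophila melanogaster larvae of the white-eyed laboratory strain w1118. Per the labels, each array carried RNA pooled from 10 larvae that had fed for 5 days, starting as eggs, on a semi-purified diet. The control group ate this diet alone. In the other group, palm fruit juice (PFJ) was mixed into it. The labels give its dose as 4 ml, as 19000 mg of gallic acid equivalents per kg of diet and as 0.86 mg per kcal. These values were not reconciled here. Gallic acid equivalents express the phenolic content of a mixture. Each group had 2 arrays, and each replicate was a separate pool of larvae. Biotin-labelled single-stranded cDNA was made from total RNA with the GeneChip WT PLUS kit, per the labels' protocols.

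The deposited values were log2 intensities, 1 per transcript cluster and array. Per the submitters' processing notes, they were made with Affymetrix Expression Console 1.4.0.38 and RMA, a method that corrects probe background, makes the arrays' probe distributions equal and summarises the probes of each cluster. The log2 scale was read from the values, which ran from 1.36 to 12.7. The column medians were 4.09 and 3.93 in control replicates 1 and 2 and 4.08 and 4.00 in PFJ replicates 1 and 2. The genome build and annotation were not given in the sources used here, so no coordinates are printed. RMA assumes that most genes do not change, so a shift shared by most genes would not be seen. Probe-level values were not analysed here, so no detection call against background was made. The number of arrays limits the precision.

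Of the 16322 rows, 13441 had 1 gene symbol in the platform annotation table, 555 had several and 2326 were not in that table and stayed unnamed. Rows with several symbols or none were left out of the main test. Of the rows with 1 symbol, 13244 had an Entrez identifier and 13064 of these matched a current gene record, which changed 0 symbols. For 37 genes with several rows the row with the highest mean over the 4 arrays was kept, which left 13402 genes.

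The PFJ arrays were compared with the control arrays in R 4.3.3 with limma 3.58.1, using lmFit and eBayes on the deposited values as they were, two-sided, with no covariate. Benjamini-Hochberg adjustment ran over the 13402 genes and the threshold was an adjusted p of 0.05. Each group's SD is over its 2 arrays and each SE is the moderated one, with 4.01 degrees of freedom. Gene lists were tested with limma's camera, which asks whether a list ranks apart from the other genes, at its preset inter-gene correlation of 0.01, with adjustment over 38 lists that had at least 3 measured members. A correlation estimated per list, and limma's fry, were alternatives.

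The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose PFJ arrays both lay on one side of both control arrays. Where fewer passed, the smallest unadjusted p in that direction filled the places. For a described list, up to 4 members with the smallest unadjusted p could be named.

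The lists covered lipid synthesis and storage, lipolysis and fatty acid oxidation, glycolysis and gluconeogenesis, glycogen and trehalose, pentose phosphate and NADPH supply, the citrate cycle, secreted fat body proteins, and insulin, TOR and FOXO signalling. Further lists held antimicrobial and bomanin peptides, immune recognition and signalling, Turandot and JAK-STAT genes, heat shock proteins, ER stress and secretory chaperones, antioxidant enzymes, glutathione S-transferases, cytochrome P450s, UDP-glycosyltransferases, metal handling and amino acid catabolism. Cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, the proteasome, peroxisome biogenesis, autophagy, DNA replication and endocycle, the ecdysone response, the circadian clock and male dosage compensation were also tested. Markers of other tissues covered salivary gland, midgut, muscle, hemocyte, oenocyte and tubule, testis, cuticle and epidermis, imaginal disc and neuron. The lists held 857 measured genes, 4 of them in more than 1 list. Members without a row of their own under a single symbol, such as Sod1, Hsp83 and the Lsp1 genes, were not analysed here.

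The procedure was tested on simulated data for the 13402 genes, with 200 genes changed by known amounts. With gene spreads drawn from the fitted prior, limma's adjusted test called 0 of 50 genes changed by 1 on the log2 scale, 22% of those changed by 2, 68% by 3 and 86% by 4, along with 2 of 13202 unchanged genes. A first version gave each gene its own moderated spread and called 0%, 82%, 94% and 100% at the same sizes, along with 14 unchanged genes beside 138 changed ones. The version drawn from the prior was added after that share of false calls was seen, and recovery therefore depends on the spread assumed. Recovery also depends on how many genes were changed, since the adjustment is milder where more genes have small p-values. The simulated genes varied independently of each other. In both versions a list shifted by 0.50 passed camera at the preset correlation and 0 of the 37 other lists did. This run therefore does not show how often the preset correlation calls lists falsely where genes vary together. With an estimated correlation the shifted list had adjusted p of 0.978 and 0.986, so that setting did not recover a shift of this size.

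The other settings tried were quantile normalisation repeated, median centring, 2 filters on dim genes, the replicate number as a block, the mean of a gene's rows, array weights, a trended and robust variance prior, all rows, a minimum change of 1.5-fold, and leaving out each array in turn. The mean of the testis list or of the midgut list as a covariate was added after seeing the data.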

Results

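Expression was measured in fat bodies, the larval organ that stores fat and glycogen and secretes most proteins of the hemolymph. Larvae of 5 days had eaten a semi-purified diet with or without palm fruit juice (PFJ), an extract rich in phenolic compounds. Each group had 2 arrays, and each array held RNA pooled from 10 larvae. Values are RMA log2 intensities, for 13402 genes. The comparison asked which transcripts differ between larvae fed PFJ and controls.

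The arrays of a group were no closer to each other than the closest arrays of different groups. Across genes, which are not independent replicates, Pearson's r was 0.910 between the control arrays and 0.961 between the PFJ arrays, and it lay between 0.920 and 0.968 for arrays of different groups. The control arrays were over 2-fold apart in 1324 genes and the PFJ arrays in 756. The first principal component held 63.8% of the variance and set control replicate 2, at 55.6, apart from control replicate 1 at -34.6, PFJ replicate 1 at -25.5 and PFJ replicate 2 at 4.56. Control replicate 2 had 118 genes at least 2 log2 units below each other array, against 5 for control replicate 1, 4 for PFJ replicate 1 and 0 for PFJ replicate 2. Of the 22 measured genes of the testis list, 3 were among these. Mst77F, a sperm chromatin protein gene named after its values were seen, read 3.21 in control replicate 2, against 9.13 in control replicate 1, 8.51 in PFJ replicate 1 and 7.70 in PFJ replicate 2.

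The genes with the smallest p-values included a heat shock gene, an antifungal peptide gene and chitin-binding protein genes, but no single gene passed the adjusted test. Hsp70Bbb, a copy of the stress-inducible Hsp70 chaperone, averaged 6.20 ± 0.30 in controls and 9.02 ± 0.33 with PFJ (SD, n = 2 each), a 7.07-fold difference. Drsl5, of the drosomycin family of antifungal peptides, averaged 5.33 ± 0.16 and 7.31 ± 0.10, a log2 difference of 1.99 (SE 0.18). The largest difference among the named genes belonged to CG17105, at 4.33 (SE 0.55), or 20.1-fold. Paics, an enzyme gene of de novo purine synthesis, differed by 1.22 (SE 0.17). In the other direction, CG43896 averaged 8.15 ± 0.03 in controls and 6.39 ± 0.02 with PFJ, a log2 difference of -1.76 (SE 0.16). The chitin-binding obstructor genes obst-G and obst-J differed by -1.31 (SE 0.16) and -1.49 (SE 0.19). The gene slbo, which encodes the fly C/EBP transcription factor, differed by -1.27 (SE 0.17). The remaining higher genes were CG34244, Srg1, CG16713, CG16926, CG42500, CG16704, CG3397 and CG32249, with log2 differences from 1.49 to 2.09. The remaining lower ones were CG8492, CG7017, CG7567, CG6231, CG15890, CG5404, CG7715 and the cuticle protein gene Cpr49Ag, from -0.96 to -2.18.

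**Figure D1:**
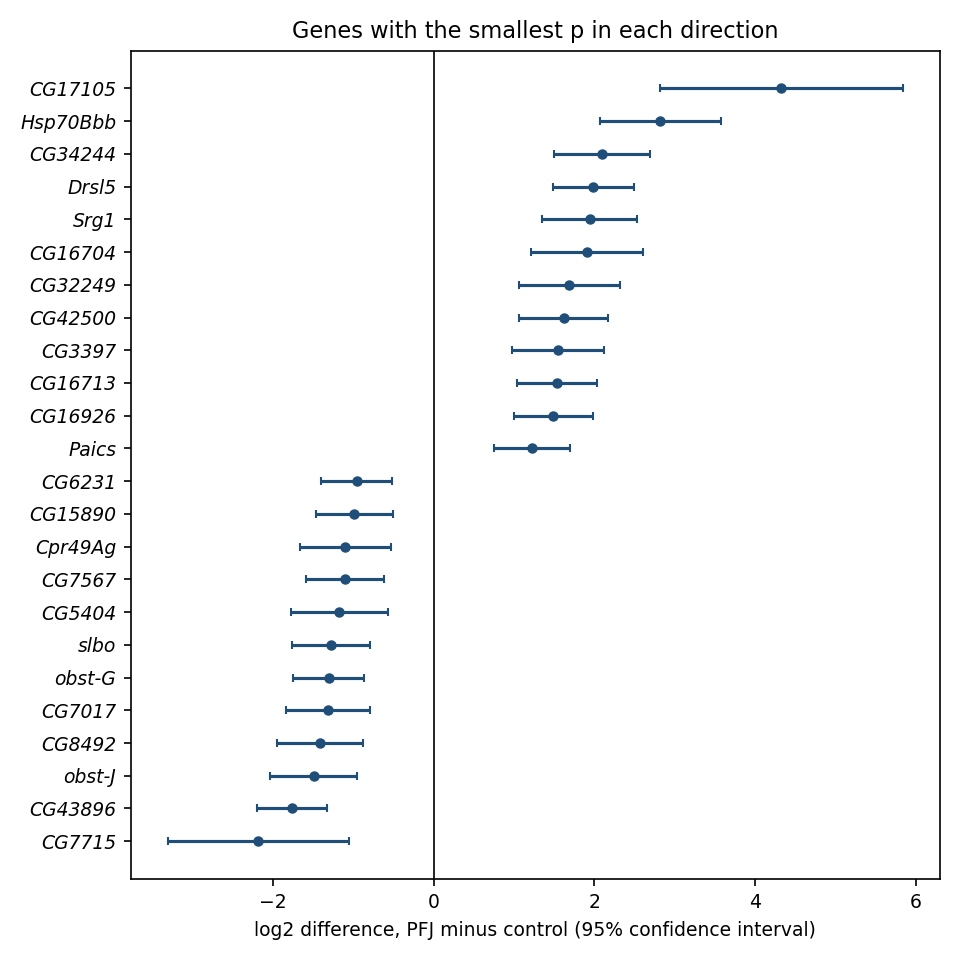
Log2 difference (PFJ minus control, horizontal axis) of the 24 genes with the smallest unadjusted p-values, 12 in each direction, from 2 arrays per group. Points are differences and bars are 95% confidence intervals from limma; no gene passed adjustment over the 13402 genes, and CG17105, at 4.33, lies farthest to the right.

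Limma gave 0 genes higher and 0 lower at an adjusted p under 0.05, with the smallest adjusted p at 1. At an unadjusted p under 0.05 there were 373 genes, 233 higher and 140 lower, against 670.1 expected by chance. Both PFJ arrays lay above both control arrays in 2077 genes and below them in 1758, together 28.6% of genes, where chance gives 33.3%. With 2 arrays against 2, an exact permutation test cannot reach the threshold for any gene. The median SE was 0.22 on the log2 scale, and without control replicate 1 the unadjusted count was 945, without PFJ replicate 2 it was 566, and 0 genes passed adjustment in either case.

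As groups, 18 of the 38 lists ranked apart from other genes by camera with its preset correlation, 16 higher and 2 lower with PFJ. None of them passed with a correlation estimated per list, where the adjusted p was 0.647 for each of the 18, nor by fry's directional test. The same preset test also called lists in groupings that mix the diets. It called 13 lists when the replicate 1 arrays were set against the replicate 2 arrays, and 10 when the arrays were crossed. The count was 5 without PFJ replicate 2, 10 without control replicate 1, 14 without control replicate 2 and 20 without PFJ replicate 1.

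Heat shock genes had the smallest p of any list at the preset correlation, while cuticle genes had it with an estimated one (unadjusted 0.0208 against 0.115 for heat shock). The heat shock list of 11 measured genes had a median log2 difference of 0.62 and an adjusted camera p of 4.18e-05. At unadjusted p under 0.05, 5 were higher and 0 lower, and 4 passed when adjusted over the list alone, against 0 over all genes tested. Next to Hsp70Bbb, the inducible chaperone genes Hsp68 and Hsp70Ba differed by 2.15 (SE 0.32) and 2.17 (SE 0.40). The small heat shock gene Hsp26 differed by 0.85 (SE 0.19). Hsp70 copies are nearly identical in sequence, so their separate values are uncertain. Other members, named after their values were seen, overlapped between groups, among them Hsp27 at -0.03 (SE 0.26), Hsp60A at -0.21 (SE 0.43) and the regulator Hsf at -0.13 (SE 0.18). Without PFJ replicate 2 the median of the list was 0.59 and its adjusted p 0.0998, and without control replicate 2 they were 0.29 and 0.00182. In the crossed grouping the adjusted camera p was 0.0279, and with replicate 1 against replicate 2 it was 0.979.

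**Figure D2:**
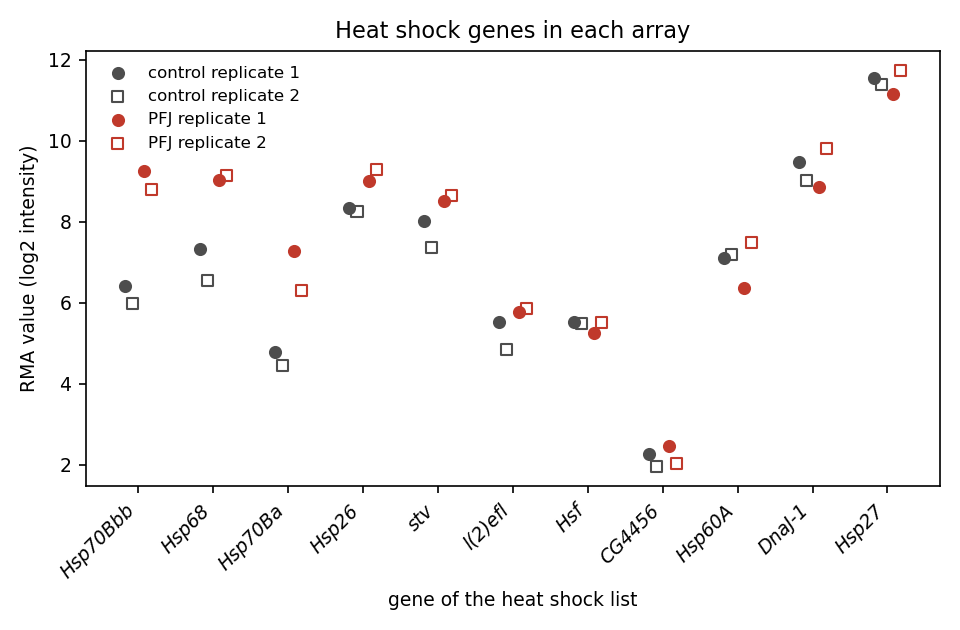
RMA log2 intensity (vertical axis) of the 11 measured heat shock genes in each of the 4 arrays. Grey marks are controls, red marks PFJ, circles replicate 1 and squares replicate 2; both PFJ arrays lie above both control arrays for 6 genes, while Hsp27, Hsp60A and Hsf overlap.

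Of the detoxification lists, glutathione S-transferases and cytochrome P450s ranked higher, and UDP-glycosyltransferases did not pass. The 35 glutathione S-transferase genes, whose enzymes couple glutathione to electrophiles, had a median of 0.23 and an adjusted p of 5.19e-05, with 29 positive and 6 negative differences. GstD10 differed by 1.65 (SE 0.40), GstE1 by 0.77 (SE 0.24), GstD2 by 0.61 (SE 0.17) and GstE9 by 0.57 (SE 0.17). The 80 cytochrome P450 genes had a median of 0.09 and an adjusted p of 0.0121, with 52 positive and 28 negative differences. Cyp4d1, Cyp6g1 and Cyp309a1 differed by 1.01, 0.96 and 0.96, and Cyp6v1 by -0.90. No gene of either list passed when adjusted over the list alone. Without PFJ replicate 2 the adjusted p was 0.244 for the transferases (median 0.15) and 0.781 for the P450s (median 0.02), and for the P450s it was 0.302 without control replicate 1 (median 0.08). With the midgut list mean as a covariate, added after seeing the data, it was 0.424 for the P450s, at a median of 0.09, and 0.0270 for the transferases, at 0.22. In the crossed grouping the transferases had an adjusted camera p of 0.0279, and with replicate 1 against replicate 2 it was 0.249. Both lists passed without PFJ replicate 1, at medians of 0.36 and 0.25. The P450s also passed with quantile normalisation repeated (median 0.05), with median centring (0.04) and with both filters on dim genes (0.17 in each). The antioxidant enzyme list, which held catalase, Sod2 and peroxiredoxins, did not pass (15 genes, median 0.02, adjusted p 0.448). Its smallest p belonged to Gclm, a subunit of the enzyme that makes the glutathione precursor, at 0.67 (SE 0.23). UDP-glycosyltransferases had a median of 0.11 over 35 genes (adjusted p 0.200), and metal handling genes did not pass (20 genes, median 0.08, adjusted p 0.189). Without PFJ replicate 1 the adjusted p was 0.00128 for both of these lists (medians 0.11 and 0.22) and 0.0450 for antioxidant enzymes (median 0.07). With quantile normalisation repeated it was 0.0363 for antioxidant enzymes (median 0.09) and 0.0409 for metal handling (median 0.16), which also passed both filters on dim genes (0.0435 and 0.0490, at medians of 0.18 and 0.14). All 3 medians were below 0 without PFJ replicate 2 (-0.03, -0.05 and -0.02 for antioxidant enzymes, UDP-glycosyltransferases and metal handling).

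Carbohydrate and energy genes formed the next group. Glycolysis and gluconeogenesis ranked higher over 14 genes (median 0.37, adjusted p 0.00123), and Pgi, the glucose phosphate isomerase gene, differed by 1.02 (SE 0.22). Glycogen and trehalose genes had a median of 0.25 over 10 genes (adjusted p 0.0109), with the glycogen branching enzyme gene AGBE at 0.64 (SE 0.17). The 7 pentose phosphate and NADPH genes had a median of 0.20 (adjusted p 0.0175). Taldo, the transaldolase gene, differed by 1.02 (SE 0.18) and was the member that passed when adjusted over that list alone. Amino acid catabolism had a median of 0.17 over 15 genes (adjusted p 0.0175), with the ornithine aminotransferase gene Oat at 0.94 (SE 0.18). Oxidative phosphorylation had a median of 0.16 over 71 genes (adjusted p 0.000130), with 57 positive differences. The median of this list was 0.28 log2 units lower in control replicate 2 than in the mean of the other arrays, and its difference was 0.05 without control replicate 2, 0.29 without control replicate 1 and 0.25 with the midgut covariate. Lipolysis and fatty acid oxidation had a median of 0.20 over 14 genes (adjusted p 0.0468). Without PFJ replicate 2 the adjusted p was 0.655 for glycolysis and for amino acid catabolism, 0.718 for glycogen and trehalose, 0.444 for pentose phosphate, 0.150 for oxidative phosphorylation and 0.987 for lipolysis. The medians were then 0.30, 0.08, -0.02, 0.22, 0.19 and -0.05 in the same order, so those of glycogen and trehalose and of lipolysis turned, and those of pentose phosphate and oxidative phosphorylation stayed as large. Without control replicate 2 the adjusted p was 0.856 for oxidative phosphorylation, 0.142 for pentose phosphate (median 0.16) and 0.0753 for glycogen and trehalose (median 0.24). Without control replicate 1 it was 0.653 for lipolysis (median 0.15), 0.193 for amino acid catabolism (median 0.13), 0.0977 for pentose phosphate (median 0.20) and 0.0821 for glycogen and trehalose, whose median was larger, at 0.53. With the midgut covariate the medians were 0.31 for glycogen and trehalose (adjusted p 0.283), 0.26 for pentose phosphate (0.193), 0.29 for glycolysis (0.0924), 0.10 for amino acid catabolism (0.299) and 0.01 for lipolysis (0.770). Without PFJ replicate 1, glycogen and trehalose, pentose phosphate and lipolysis passed at larger medians of 0.46, 0.35 and 0.32. With both filters on dim genes glycogen and trehalose passed at 0.12.

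Lipid synthesis and storage did not pass (18 genes, median 0.10, adjusted p 0.161), although FASN1, a fatty acid synthase gene, differed by 1.23 (SE 0.31). The list passed with quantile normalisation repeated (median 0.12, adjusted p 0.0120), with the stricter filter on dim genes (0.07, 0.0468), without control replicate 2 (0.22, 0.0457) and without PFJ replicate 1 (median 0.37, adjusted p 0.000119), and its median was -0.09 without PFJ replicate 2 and -0.02 without control replicate 1. The citrate cycle did not pass (10 genes, median -0.08, adjusted p 0.759). It ranked higher without PFJ replicate 1 (median 0.37, adjusted p 0.000681) and lower without PFJ replicate 2 (median -0.34, adjusted p 0.00405). Secreted fat body proteins did not pass (13 genes, median 0.12, adjusted p 0.119), with Obp99b at 1.26 (SE 0.27) and the transferrin gene Tsf1 at 1.78 (SE 0.60). They passed with quantile normalisation repeated (median 0.26, adjusted p 0.0163), with the milder and stricter filters on dim genes (0.12, 0.0426 and 0.25, 0.00765) and without PFJ replicate 1 (0.17, 0.00415), and their median was -0.07 without PFJ replicate 2. Insulin, TOR and FOXO signalling had a median of 0.03 over 19 genes, a mean of -0.01 and a test direction that was lower (adjusted p 0.959).

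Immune genes were split. The 21 antimicrobial and bomanin peptide genes ranked higher (median 0.06, adjusted p 0.0175). Drsl5 passed when adjusted over the list alone, DptB differed by 0.67 (SE 0.17), CecB by 0.65 (SE 0.16) and AttD by 0.70 (SE 0.20), while Mtk, named after its value was seen, differed by -0.62 (SE 0.21). Of these 21 genes, 5 were above the median level of all genes. The median of the list was 0.02 without control replicate 1 (adjusted p 0.197), 0.20 without control replicate 2 (0.0665), 0.02 without PFJ replicate 1 (0.161) and 0.11 without PFJ replicate 2 (0.0363). Repeating the quantile normalisation took its median to -0.04 (adjusted p 0.144) and the stricter filter on dim genes took it to -0.08 (adjusted p 0.529). With the midgut covariate it was 0.05 (adjusted p 0.0924). The list passed at a median of 0.01 with median centring, 0.21 with the milder filter and 0.09 with the testis covariate, which was also added after seeing the data. The list passed in 7 of 13 other settings at the preset correlation. Immune recognition and signalling did not pass (18 genes, median 0.16, adjusted p 0.112), nor did the Turandot and JAK-STAT list (6 genes, median 0.07, adjusted p 0.394). The recognition list passed with quantile normalisation repeated (median 0.13, adjusted p 0.0147), without control replicate 2 (0.21, 0.0288), without PFJ replicate 1 (0.29, 0.00208) and with the testis covariate (0.16, 0.0250). Its median was -0.06 without PFJ replicate 2.

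Markers of other tissues moved with the groups or within them. Midgut genes, mostly digestive enzymes, had a median of 0.46 over 41 genes (adjusted p 0.00118). Their mean level was 4.88 in control replicate 1, 5.95 in control replicate 2, 5.42 in PFJ replicate 1 and 6.29 in PFJ replicate 2, so the gap within controls (1.08) and within PFJ (0.87) exceeded the mean difference between groups (0.44). LManV, a mannosidase gene, differed by 2.42 (SE 0.87) and Mur29B by -0.76 (SE 0.27). Hemocyte markers had a median of 0.35 over 13 genes (adjusted p 0.0109), and the prophenoloxidase genes PPO1 and PPO2 differed by 1.26 (SE 0.29) and 0.78 (SE 0.25). Other markers, named after their values were seen, had negative differences. These were NimC1 and crq at -0.67 each (SE 0.43 and 0.44), Ppn at -0.09 and Pxn at -0.01. Muscle genes had a median of 0.54 over 12 genes (adjusted p 0.0478) and 0 members at unadjusted p under 0.05. The 110 cuticle and epidermis genes had a median of 0.13 (adjusted p 4.18e-05). Cpr67B differed by 1.19 (SE 0.19), Cpr49Ag by -1.10 (SE 0.20) and TwdlX by 0.65 (SE 0.16). Of these 110, 17 were above the median level of all genes. The median of the list was 0.04 with quantile normalisation repeated (adjusted p 0.0187) and 0.08 with median centring, and among the members left by the milder and stricter filters on dim genes it was 0.17 and 0.41 (adjusted p 0.000984 with the stricter one). This list passed in all 13 other settings run at the preset correlation, as no other list did. In the groupings that mix the diets its adjusted camera p was 0.505 (crossed) and 0.824 (replicate 1 against replicate 2). With an estimated correlation it was 0.647 for PFJ against control. The 4468 dimmest genes had a median log2 difference of 0.07 and the 4467 brightest -0.10.

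The male dosage compensation genes, roX1, roX2 and msl-2, had a median of 0.97 over 3 genes (adjusted p 0.0310). The male-specific RNA roX1 read 8.58 and 5.95 in controls and 9.30 and 8.69 with PFJ. For roX2 the values were 2.52 and 2.06 against 3.71 and 2.80, while msl-2 overlapped between groups. The labels give no sex, so a different share of male larvae cannot be told apart from the diet here. Without PFJ replicate 2 the adjusted p was 0.655 for midgut (median 0.09), 0.244 for hemocyte (0.20), 0.721 for muscle (0.14) and 0.0966 for male dosage compensation, whose median was larger, at 1.42. Without control replicate 1 it was 0.50 for midgut (median -0.09) and for hemocyte (0.16). Without control replicate 2 it was 0.856 for muscle (median -0.00056) and 0.241 for male dosage compensation (0.41), and without PFJ replicate 1 it was 0.161 for the latter (0.51). Midgut passed at medians of 1.00 without control replicate 2 and 0.91 without PFJ replicate 1, and muscle at 1.07 without control replicate 1 and 0.85 without PFJ replicate 1. With the midgut covariate the median was 0.20 for hemocyte (adjusted p 0.299) and 0.64 for muscle (0.105), and with the mean of each gene's rows it stayed at 0.54 for muscle (0.0526). Testis genes did not pass (22 genes, median 0.10, adjusted p 0.749), with array means of 4.57 and 2.95 in controls and 4.28 and 3.68 with PFJ. They ranked higher without control replicate 1 (median 0.50, adjusted p 6.59e-05), lower without control replicate 2 (median -0.52, adjusted p 4.20e-05) and higher with the midgut covariate (median 0.33, adjusted p 0.000947). Salivary gland (12 genes, median 0.03, adjusted p 0.603), oenocyte and tubule (8 genes, median -0.06, adjusted p 0.564), imaginal disc (11 genes, median -0.04, adjusted p 0.448) and neuron markers (9 genes, median -0.12, adjusted p 0.103) did not pass. Salivary gland genes passed as higher without control replicate 2 (median 0.36, adjusted p 0.00860), with a median of -0.20 without control replicate 1. Neuron markers passed as lower without control replicate 1 (median -0.45, adjusted p 0.00943) and with the midgut covariate (median -0.26, adjusted p 0.0478), with a median of 0.07 without control replicate 2.

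**Figure D3:**
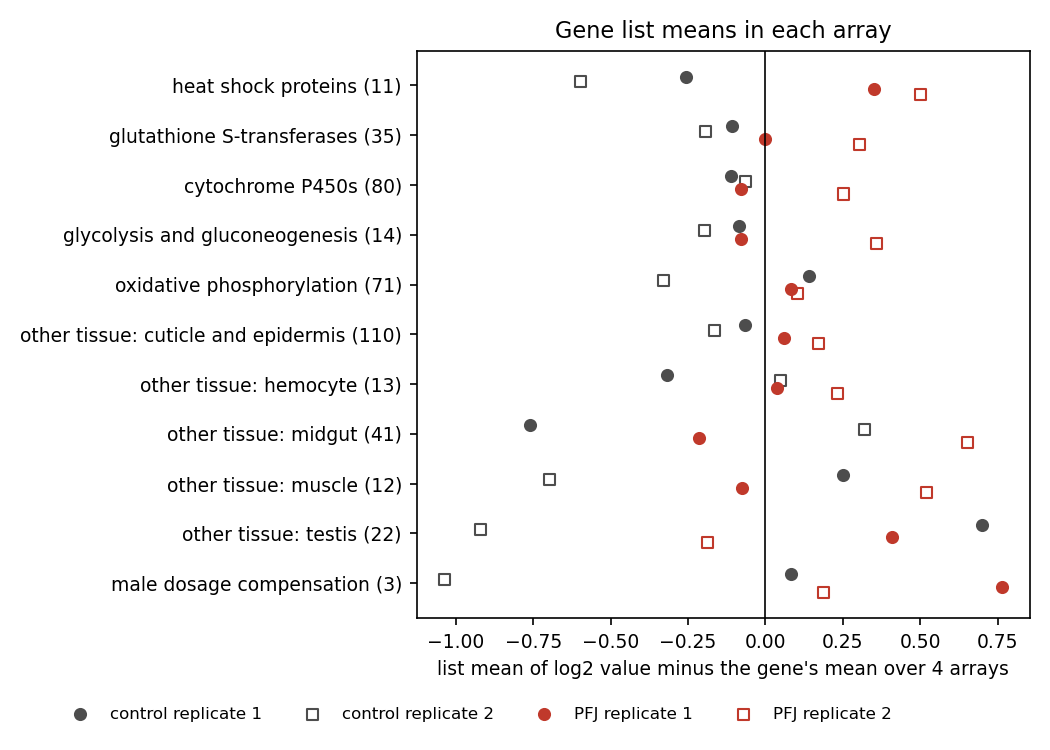
Mean of a gene list in each array after subtracting each gene's mean over the 4 arrays (horizontal axis, log2 units), for 11 lists with their number of measured genes in parentheses. Grey marks are controls, red marks PFJ, circles replicate 1 and squares replicate 2; heat shock means are -0.26 and -0.60 in controls against 0.35 and 0.50 with PFJ, while the testis mean of control replicate 2 lies at -0.92.

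DNA replication and endocycle genes and proteasome genes were the 2 lists that ranked lower. DNA replication and endocycle genes had a median of -0.24 over 18 genes (adjusted p 0.0109), 16 of them negative, with PolA1 at -0.34 (SE 0.18) and dup at -0.43 (SE 0.25). Proteasome genes had a median of -0.09 over 40 genes (adjusted p 0.0491), with Rpt4 at -0.74 (SE 0.27). The proteasome call held in 3 of 13 other settings at the preset correlation. The median was nearer 0 with quantile normalisation repeated (-0.05, adjusted p 0.448) and with the midgut covariate (-0.06, 0.299). It was farther from 0 with median centring (-0.14, 0.0644) and with the milder and stricter filters on dim genes (-0.11, 0.217 and -0.15, 0.0982). It stayed at -0.09 with the mean of each gene's rows (0.0518) and with array weights (0.0503). Cytosolic ribosomal protein genes ranked higher (42 genes, median 0.15, adjusted p 0.0149). Without control replicate 2 the adjusted p was 0.893 for DNA replication (median -0.03) and 0.241 for ribosomal proteins (0.16), and without control replicate 1 it was 0.827 for the proteasome (-0.06) and 0.0653 for ribosomal proteins (0.20). Without PFJ replicate 1 it was 0.0781 for DNA replication (median -0.14), 0.398 for ribosomal proteins (0.05) and 0.132 for the proteasome (-0.07). Without PFJ replicate 2 it was 0.0521 for DNA replication (median -0.20) and 0.150 for the proteasome (-0.09). With the stricter filter on dim genes DNA replication had a larger median of -0.34 (adjusted p 0.0923). It passed at -0.45 without control replicate 1, and ribosomal proteins passed at 0.26 without PFJ replicate 2. Ribosome biogenesis (19 genes, median -0.03, adjusted p 0.484), autophagy (20 genes, median -0.20, adjusted p 0.112) and the circadian clock (8 genes, median -0.05, adjusted p 0.664) did not pass. Autophagy passed as lower without PFJ replicate 2 (median -0.44, adjusted p 0.0209) and with the midgut covariate (median -0.36, adjusted p 0.00467), and its median was -0.0040 without control replicate 2 and -0.03 without PFJ replicate 1, where the test direction was higher (adjusted p 0.786). Peroxisome biogenesis had a median of -0.01 over 10 genes and a test direction that was higher (adjusted p 0.959). ER stress and secretory chaperones had a median of 0.02 over 11 genes, a mean of -0.02 and a test direction that was higher (adjusted p 0.959). The ecdysone response did not pass (20 genes, median -0.14, adjusted p 0.116), but it was 1 of 4 lists past fry's test for change in either direction (adjusted p 0.0193), and it passed as lower with the testis covariate (median -0.19, adjusted p 0.0477). Amino acid catabolism (0.0193), pentose phosphate genes (0.0266) and antimicrobial peptides (0.0266) were the others.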

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

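The gene count was 0 under every alternative run, with the smallest adjusted p at 0.31, without control replicate 1. The count at unadjusted p under 0.05 (373) was 238 with the milder filter on dim genes and 192 with the stricter one, where fewer genes were tested. It was 1039 with the midgut list mean as a covariate, an alternative chosen after seeing the data, where the cause was not tested. Leaving out 1 array in turn gave 304 to 945 genes; the lone array of a group was then assumed to vary like the other group. The list count (18) was 0 with an estimated correlation and 0 with fry, 10 with the midgut covariate and 5 to 20 with 1 array left out. The direction of the list test turned in 4 cases, and the median turned with it in 2 of them, midgut without control replicate 1 and muscle without control replicate 2. The midgut list was at 0.027 with its own mean as a covariate, which follows from its construction. Its lowest and highest values with 1 array left out were -0.0946 and 1.00, those of DNA replication -0.45 and -0.0281 (its test turned), and those of muscle -0.00056 and 1.07. Medians alone turned for glycogen and trehalose (-0.0213) and lipolysis (-0.0499) without PFJ replicate 2, and for antimicrobial peptides with quantile normalisation repeated (-0.0402) and with the stricter filter on dim genes (-0.0765). The cause was not tested. Among the 18 lists, 171 of 268 other values kept the test's direction and side of the threshold and 93 lost the call; named genes stayed outside the adjusted threshold in 335 of 335. The 20 lists that did not pass gave 298 values in other settings. In 29 of these a list passed in its own direction, and in 2 the other way (testis without control replicate 2 and the citrate cycle without PFJ replicate 1). In 43 the direction turned without a call. Calls came from 12 of the 20 lists. The replicate numbers had a correlation of deviations of 0.34 in 2 pairs and were not taken as pairing the pools. Replicate 1 against replicate 2 gave 1462 genes at unadjusted p under 0.05 by limma, and the crossed grouping 303, with 0 past adjustment in either. The replicate number thus went with a larger difference than the diet did (373). In both groups the midgut mean was higher and the testis mean lower in replicate 2. With the replicate block, 0 genes and 17 lists passed: lipolysis (adjusted p 0.0706) and muscle (0.0790) lost their calls and autophagy (0.0178) gained one, at medians that the block left as they were. With the block 547 genes had unadjusted p under 0.05. Dim genes lie near the lowest values of the arrays, where signal over background limits what can be seen.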

Other observations

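The tests of the obstructor and mucin set, of heat shock without the Hsp70 copies, of the midgut covariate and of transferases within pairs of arrays were chosen after the results were seen. The purine and testis questions also arose from values in these data, and their predictions were written before those tests. Leaving out arrays and estimating the correlation were fixed beforehand, but weighing explanations by them was not. Prat2 and the mucin genes were also named after their values were seen. The set tests are model-based, since no exact permutation of 2 arrays against 2 can reach the threshold. Several genes of de novo purine synthesis had small unadjusted p-values. Paics (1.22) was accompanied by Prat2, for the first enzyme of the pathway, at 0.98 (SE 0.16), by Gart at 0.97 (SE 0.18) and by Pfas at 0.54 (SE 0.19), none of which passed over all genes. The hypothesis that the pathway was higher as a group with PFJ was tested on its 5 other measured genes, Prat, Gart, Pfas, ras and bur. Their unadjusted camera p was 0.114, with 3 of 5 positive, and it was 0.473 with an estimated correlation. A missed threshold over so few genes, with bur at -0.56 (SE 0.47) and Prat at -0.18 (SE 0.22), leaves the hypothesis undecided.

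Some chitin-binding and mucin-type genes, families that contribute to the lining of the gut or to cuticle, had negative differences, none past adjustment. Muc96D differed by -1.92 (SE 0.52), Muc26B by -1.89 (SE 0.37), Muc68E by -1.20 (SE 0.26) and obst-I by -0.85 (SE 0.20). The hypothesis was that the obstructor and mucin families were lower as a group with PFJ. Over 25 measured family genes, without obst-G and obst-J, the median was -0.19 and limma's camera gave an unadjusted p of 0.00648. The list included genes already seen among the low ones, 14 of 25 were negative, and p was 0.119 with an estimated correlation, so it stays a hypothesis. The midgut list, mostly digestive enzymes, had a positive median over the same arrays. Mur29B, at -0.76, belonged both to that list and to the obstructor and mucin set.

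Some testis transcripts were far lower in control replicate 2 than elsewhere, namely 3 of the 22 list genes by at least 2 log2 units against each other array. In contrast, CycB3 read 7.05 there, above the other arrays, and aly, tomb and vas were low in all 4. The gene ocn read 6.89, 2.20, 6.86 and 5.34 and betaTub85D 7.73, 2.96, 6.94 and 5.81 in control replicates 1 and 2 and PFJ replicates 1 and 2. Of the ribosomal protein and oxidative phosphorylation medians, the farther from 0 was -0.281 against the other arrays. RMA had made the arrays' probe distributions equal beforehand, so these medians cannot decide on an array-wide loss of signal. A pool with more female larvae may account for the low testis transcripts. The mean of the male-specific roX RNAs lay 1.55 log2 units below the lowest of the other arrays. Dissection that left out the testes stays open, since roX1, though below the 8.58 of control replicate 1, still read 5.95 there. Testis and roX means also did not always go together. PFJ replicate 2 had a lower testis mean than control replicate 1 (3.68 against 4.57) but a roX mean of 5.75 against 5.55. The labels give no sex, so the makeup of the pool was tested from these RNAs. The mean of 35 Y-linked genes was not part of that test and lay near the lowest values of the arrays. It was also lowest in control replicate 2, at 2.32. It was 2.75 in control replicate 1 and 2.78 and 2.56 in PFJ replicates 1 and 2.

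The heat shock list was higher with PFJ in both arrays. Without the Hsp70 copies its unadjusted camera p was 0.0018 at the preset correlation, but the genes left were split. Hsp68, stv, Hsp26 and l(2)efl lay higher in both PFJ arrays, by 2.15, 0.89, 0.85 and 0.62. This argues against shared probes of the Hsp70 copies as the whole cause. CG4456, DnaJ-1, Hsp27, Hsf and Hsp60A overlapped between groups, at 0.14, 0.09, -0.03, -0.13 and -0.21. Without control replicate 2 the list still ranked higher, but its median fell from 0.62 to 0.29, so part of the difference rests on that array. With the midgut mean as a covariate the adjusted p was 0.00168 and the median 0.78. At the same preset correlation the list also passed in the crossed grouping, which mixes the diets (adjusted p 0.0279). A pass with so few arrays therefore does not decide on uneven gut tissue. Handling or heat during dissection could give the same pattern and was not tested, and a response to the diet stays equally open. Over the alternatives run the adjusted p ranged from 1.68e-07 to 0.0998 at the preset correlation, and was 0.647 with an estimated one.

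For glutathione S-transferases, which are also expressed in gut, uneven gut tissue was not settled. Control replicate 2 exceeded control replicate 1 in midgut genes by 1.08, yet its transferase mean was lower, at -0.0845 (95% confidence interval over genes -0.24 to 0.07), where that explanation predicted 0.74. Between the PFJ arrays, where midgut genes differed by 0.87, the transferase mean went the same way, by 0.31 (0.14 to 0.48), and each of these is 1 array against 1. With the midgut covariate the list kept a median of 0.22 and an adjusted p of 0.0270, close to the 0.0279 of the crossed grouping. The pattern may rest largely on PFJ replicate 2, since without it the median was 0.15 and the adjusted p 0.244 while the list passed without each other array; that pool's makeup and the diet both stay open.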
